A study of Mus musculus with 27 samples.

How the data were processed

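The data are gene counts from total RNA of C2C12 myotubes at 9 time points from 12 to 60 h after a serum pulse, with 3 libraries at each. Per the labels' protocols, cells were grown in 10% FBS, plated at 50000 per well, differentiated in 2% horse serum and pulsed with 50% horse serum for 2 h; ribosomal RNA was removed and the libraries were stranded. No culture without the pulse was included. The authors deposited 1 table of raw counts (whole reads per gene, not normalized) for 20446 Ensembl genes in 27 libraries. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.4.0 and cutadapt 1.9.1, the genome was mm10 and reads were counted with featureCounts. The aligner, the annotation release and the counting options are not given in the sources used here. Names, positions, lengths and GC content came from GENCODE M21 on mm10, which matched 20318 genes, 20280 of them protein-coding; 128 had no match. The table has 0 mitochondrial genes and 3717 genes without a read.

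Libraries were grouped by the time point and replicate number of their titles. Depth was 15.2 to 26.6 M counts (a 1.75-fold range, median 20.9 M). Genes passed edgeR's filterByExpr with a minimum count of 10, which kept 12687 and left out 7759. Scaling was by TMM (factors 0.979 to 1.03), and CPM (counts scaled to library size) on the log scale used a prior count of 2. The biological coefficient of variation from the common dispersion of all genes was 11.8%. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, statmod 1.5.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

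All main tests were edgeR quasi-likelihood F tests with Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Change of any shape was tested with the time point as a factor (8 contrasts), and 60 h against 12 h in the same fit. The rhythm (2 terms, cosine and sine of a 24 h period) and the linear trend (given per 48 h) were tested in 1 model with both. The peak hour is counted from the pulse, modulo 24 h. A model with an offset and separate waves for the first day (12 to 30 h) and the second (36 to 60 h) tested whether the wave differed between them. Gene lists written before the data were examined, 43 in all, were tested along the trend with camera (preset correlation 0.01, and estimated), with fry, and among rhythmic genes with Fisher's exact test, and 38 lists with at least 5 tested members were used. "Adjusted over the list alone" means that p was adjusted over the members of that list only. Left out as lists were mitochondrially encoded genes, short noncoding RNA and nuclear noncoding RNA (0 members tested each), adipocyte markers (3) and neural markers (4).

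The genes named were chosen by a rule written before the data were examined. For the rhythm these were all core clock genes tested and up to 12 others with the largest swing, a mean of at least 1 CPM and peaks within 4 h on both days. For the trend they were the 10 genes each way with the largest 60 h against 12 h change, called by both tests in the same direction, with a mean of at least 1 CPM and no overlap between the replicates of 12 and 60 h. For the days they were the core clock genes and the 6 genes with the smallest p, and for each list up to 4 members with the smallest p. Predicted genes, pseudogenes and genes of short RNAs were not named, and some genes that the rule chose are not reported here.

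The scripts were tested on simulated counts for 12621 genes (seed 1). Each fold was given to 25 genes, or to 20 for the difference between the days. Counts were drawn independently for each library, without effects shared by a replicate number or a time point. Rates in the real libraries may thus differ. The rhythm was recovered for 68%, 84%, 100% and 100% of genes changed 1.3, 1.5, 2 and 3-fold, the trend for 48%, 84%, 88% and 100%, any change for 24%, 56%, 92% and 92%, and 60 h against 12 h for 20%, 60%, 92% and 92%. A difference between the days was recovered for 5%, 65% and 85% at 1.5, 2 and 3-fold. Among 12361 unchanged genes 4, 1, 7, 3 and 1 were called by these tests in that order. The test for alternation, described under the other observations, recovered 60%, 68%, 100% and 100% at 1.2, 1.3, 1.5 and 2-fold and called 2 of 12521 unchanged genes.

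Alternatives planned before the data were examined were DESeq2 and limma-voom, median of ratios scaling, no filter and a stricter filter (mean of 1 CPM), the replicate number as a block, each library left out, adjusted p under 0.01, periods of 20, 22, 26 and 28 h, no linear or a quadratic term, a minimum swing of 1.5-fold, time point means in limma, fits without 12 h or 60 h, the 6 end libraries alone, no day offset, no 24 h terms and estimated correlations. Chosen after the data were seen were a cubic term, a decay term with a time constant of 12 h, the block with the decay term, fits from 24 h on, fits without the 9 libraries numbered 2, and lists and any change without 12 h. Groups were also redrawn 100 times. The closing section gives their effect.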

Results

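C2C12 cells, a mouse myoblast line that fuses into myotubes when serum is lowered, were differentiated in 2% horse serum and then given 50% horse serum for 2 h, a pulse that brings the circadian clocks of cultured cells into a common phase. Total RNA without ribosomal RNA was sequenced in stranded libraries at 9 time points, from 12 h to 60 h after the pulse in steps of 6 h, with 3 libraries at each (27 in all). The libraries held 15.2 to 26.6 M counted reads (median 20.9 M), and 12687 of the 20446 genes in the table had enough reads to be tested. Libraries of a time point differed by more than sampling noise in every pair (lowest chi-square per degree of freedom 5.81), so none looked like a second sequencing run of the same library, and each was counted as a replicate. Nothing states that the 3 libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The first principal component held 27.3% of the variance and the second 18.7%. Time explained 0.571 of the first and the replicate number 0.382, and for the second these shares were 0.463 and 0.478. Every time point has 1 library of each number.

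The first comparison asked which transcripts follow a 24 h wave, since the study is about circadian control in myotubes. All 7 genes with a rhythm belonged to the circadian clock or its direct outputs. Dbp, a transcription factor switched on directly by the clock, had the widest swing, with a fitted peak-to-trough ratio of 2.25 (log2 1.17 ± 0.11, SE, 27 libraries; edgeR adjusted p = 4.33e-06) and a peak at 20.4 ± 0.357 h of the cycle. The level of Dbp was 8.88 ± 0.552 CPM (counts scaled to library size, SD, n = 3) at 12 h, 13.9 ± 1.33 at 18 h, 6.19 ± 0.376 at 30 h, 13.5 ± 1.69 at 48 h and 6.93 ± 0.248 at 54 h. Per2 and Per3, repressors of the feedback loop, swung 1.79-fold (log2 0.84 ± 0.10, adjusted p = 7.2e-05) and 1.64-fold (0.71 ± 0.12, adjusted p = 0.0131), with peaks at 23.4 and 22.7 h. Arntl, which encodes BMAL1, the activator that works with CLOCK, ran nearly opposite to Dbp, with a ratio of 1.41 (log2 0.50 ± 0.08, adjusted p = 0.00378) and a peak at 8.95 ± 0.575 h.

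Nr1d2, which encodes the nuclear receptor REV-ERB beta, a repressor of Arntl, had a ratio of 1.52 (log2 0.61 ± 0.07, adjusted p = 4.36e-05) and its highest means at 18 h (93.0 CPM) and 42 h (89.7). Cry1, a partner of the PER proteins, peaked later, at 1.81 h, with a ratio of 1.33 (log2 0.41 ± 0.05, adjusted p = 2.65e-04). Tef, a relative of Dbp, had a ratio of 1.31 (log2 0.39 ± 0.06, adjusted p = 0.00208) and a peak at 21.7 h. Among the 9 libraries of each replicate number alone, the ratio of Dbp was 2.03, 2.31 and 2.47, that of Per2 1.79, 1.77 and 1.83, and that of Arntl 1.42, 1.43 and 1.40. On mm10, Dbp (ENSMUSG00000059824) lies on chromosome 7 from 45705088 to 45710203, Per2 (ENSMUSG00000055866) on chromosome 1 from 91415982 to 91459324, and Arntl (ENSMUSG00000055116) on chromosome 7 from 113207465 to 113314126.

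**Figure D1:**
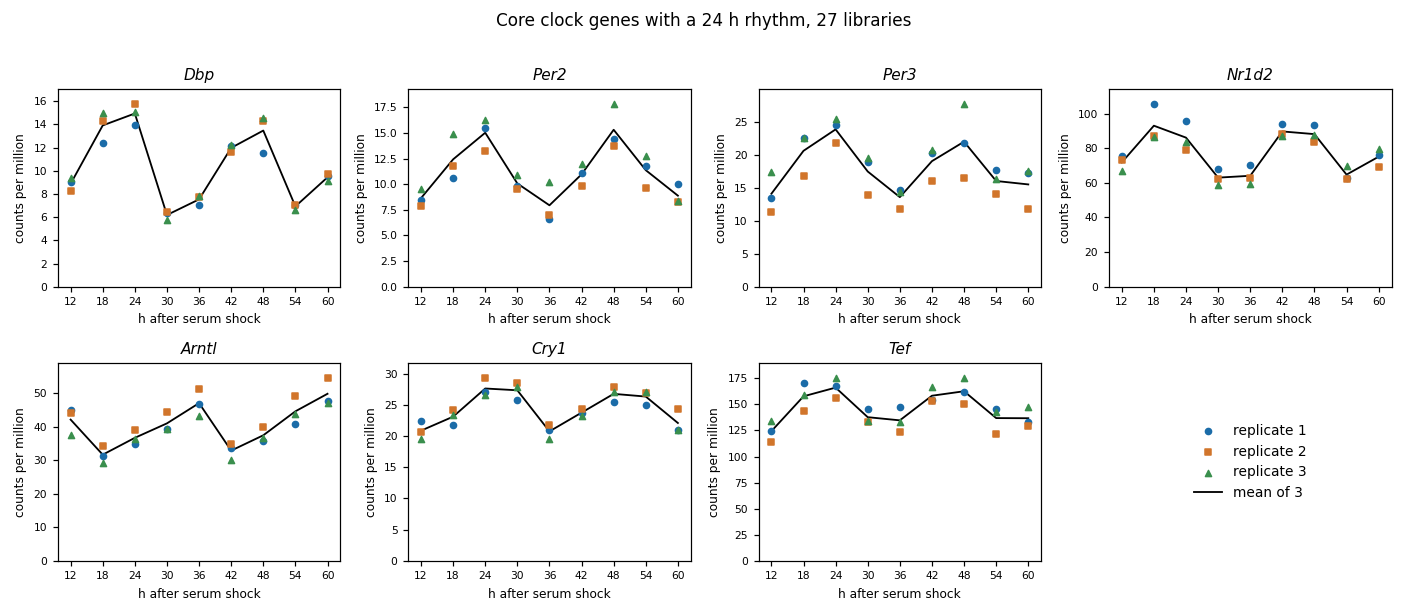
CPM of the 7 rhythmic clock genes (vertical axes, from 0) against hours after the serum pulse (horizontal axes); points are single libraries, with symbols for the 3 replicate numbers, and lines join the means of 3 libraries. Dbp peaks near 20.4 h of each cycle and Arntl near 8.95 h.

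The other clock genes did not pass over all genes tested. Nr1d1, which encodes REV-ERB alpha, had a log2 swing of 0.51 ± 0.28, Per1 0.41 ± 0.17, Ciart 0.44 ± 0.17, Cry2 0.23 ± 0.11, Npas2 0.13 ± 0.31, Bhlhe40 0.16 ± 0.12, Clock 0.07 ± 0.06 and Rora 0.05 ± 0.12. Adjusted over the list alone, 11 of the 19 core clock genes passed, and those added include Nfil3 (0.23 ± 0.06), Bhlhe41 (0.23 ± 0.07) and the weakly expressed Hlf (1.19 ± 0.35 at a mean of 0.294 CPM). The core clock list was the 1 list of 38 enriched among rhythmic genes, with 7 of 19 members (Fisher's exact test, two-sided, adjusted p = 1.83e-19). That test takes members as independent, which clock genes are not, so its p is too small. When whole time points were shuffled with their libraries kept together, 7 core clock genes were called in 1 of 100 shuffles. At least 1 list of any kind was called in 62 of them, though such shuffles also break up linear trends, which can then be fitted as waves. Adjusted over the list alone, 12 of 37 proliferation genes (Cenpa, 0.60 ± 0.13), 12 of 24 ATF4 targets (Ddit3, 0.48 ± 0.11), 2 of 14 glucocorticoid targets, 2 of 6 osteoblast markers and 1 of 22 genes of the unfolded protein response also passed, though not over all genes. These p-values were not adjusted across the 38 lists. As whole lists, the 2 largest did not return to the same level after 24 h. The median log2 level of ATF4 targets, centred per gene, was 0.575 at 12 h, -0.103 at 36 h and 0.027 at 60 h. That of proliferation genes was -0.094 at 24 h and 0.131 at 48 h.

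In total 570 genes had an unadjusted p under 0.05 for the rhythm, where 634 of 12687 unrhythmic genes would. DESeq2 called 11 genes, adding Angptl6, Cdc25c, Knstrn and Plau to the 7 (named after their values were seen). Per3, Tef and Arntl had swings of 0.67, 0.35 and 0.48 without the 12 h libraries but were then not called (adjusted p = 0.213, 0.101 and 0.0822). Per3 was also not called, with swings from 0.66 to 0.70, without the first library of 12 h (0.0541), the first or the third of 24 h (0.0542 and 0.057) or the third of 48 h (0.0986). From 24 h on, Per3, Tef and Arntl were not called (edgeR adjusted p = 0.306, 0.135 and 0.162), nor at a period of 28 h (0.245, 0.281 and 0.0837). Arntl was also lost at 22 h (0.13), and Per3 at 26 h (0.0513) and with a decay term (0.0739). With each time point taken as 1 mean, limma called 0 genes (lowest adjusted p = 0.152). In that fit 247 genes had an unadjusted p under 0.05 and all 7 clock genes were among them, while limma-voom on the 27 libraries called 7 genes.

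The next comparison asked whether the wave was the same in the first day (12 to 30 h) and the second (36 to 60 h). The fitted wave differed for 637 genes. The 6 with the smallest p had a wide fitted swing on the first day and a narrow one on the second. The first day holds few time points, so a single rise or fall there can be fitted as a wide swing. Nsdhl and Lss, enzymes of cholesterol synthesis, had a log2 swing of 1.59 ± 0.13 and 2.03 ± 0.18 on the first day and of 0.23 ± 0.12 and 0.23 ± 0.14 on the second (SE; edgeR adjusted p = 1.5e-06 and 2.47e-06). Fdft1, of the same pathway, had a swing of 0.18 ± 0.10 on the second day, a difference of -1.32 from the first (adjusted p = 2.47e-06). Lss rose from 36.0 ± 0.461 CPM (SD, n = 3) at 12 h to 150 ± 2.47 at 36 h and stood at 141 ± 7.80 at 60 h. Fdft1 rose at each step from 49.1 CPM at 12 h to 143 at 36 h and then stayed between 111 and 130. The first-day swing of Fdft1 was thus a single rise, not a wave seen to rise and fall. Elovl6, which lengthens fatty acids, had swings of 1.35 ± 0.13 and 0.24 ± 0.11 (adjusted p = 2.47e-06). Cth, which makes cysteine, and Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, both activated by ATF4, went the other way first, with swings of 2.77 ± 0.23 and 1.95 ± 0.17 on the first day and 0.22 ± 0.20 and 0.11 ± 0.12 on the second (adjusted p = 2.47e-06 for both). Cth stood at 28.4 ± 3.97 CPM at 12 h, 6.05 ± 1.33 at 24 h and 26.9 ± 2.52 at 60 h.

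None of the 7 rhythmic clock genes was called for a difference between the days, in a test that found few small differences in simulated data. Dbp had a log2 swing of 1.39 ± 0.16 on the first day and 1.05 ± 0.16 on the second (adjusted p = 0.813), Per2 0.82 ± 0.16 and 0.86 ± 0.13 (0.765), Nr1d2 0.68 ± 0.10 and 0.66 ± 0.10 (0.863), and Arntl 0.42 ± 0.11 and 0.60 ± 0.11 (0.885). Per3 had 0.74 ± 0.19 and 0.69 ± 0.17, Cry1 0.40 ± 0.09 and 0.35 ± 0.07, and Tef 0.45 ± 0.09 and 0.34 ± 0.08. Of the 637 genes, 605 also changed over the 9 time points and 290 had a linear trend. With a term that decays from 12 h added to the model, 93 genes were called, and without the 9 libraries numbered 2, 362.

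**Figure D2:**
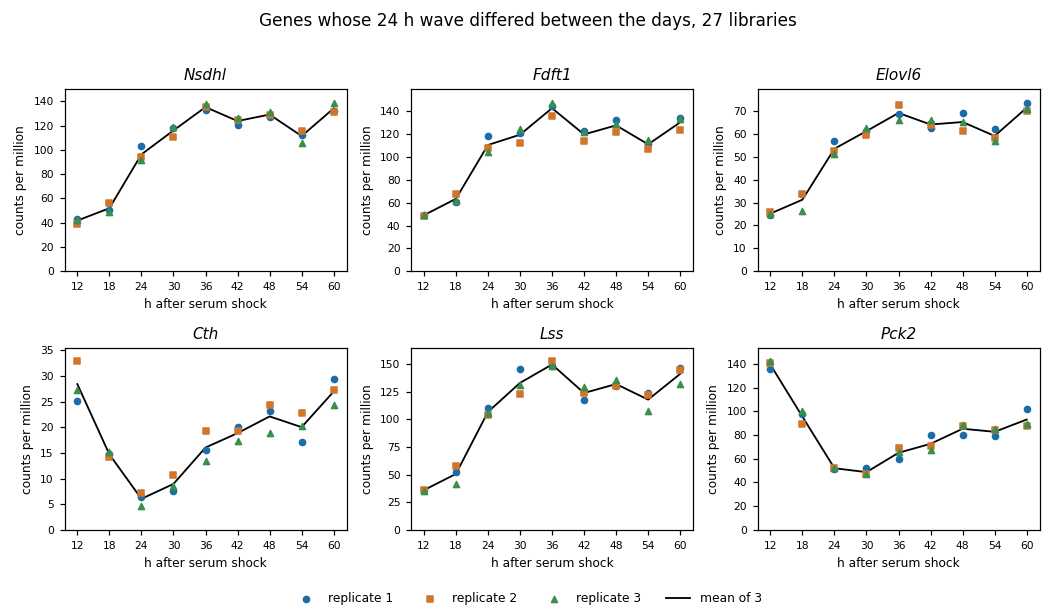
CPM (vertical axes, from 0) against hours after the serum pulse (horizontal axes) for the 6 genes with the smallest p for a wave that differed between the days; points are single libraries by replicate number and lines join means of 3. Lss goes from 36.0 at 12 h to 150 at 36 h, and Cth from 28.4 at 12 h to 6.05 at 24 h.

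Change of any shape over the 9 time points was found for 2338 genes, 18.4% of those tested (edgeR, 8 contrasts, adjusted p under 0.05). Without the 12 h libraries the count was 1189, and without the 9 libraries numbered 2 it was 1500. The 12 h and 60 h libraries are 48 h apart, at the same phase of a 24 h wave, so their contrast shows drift rather than rhythm. Against 12 h, 1203 genes were higher and 830 lower at 60 h, and a linear trend from 12 to 60 h was up for 1355 and down for 1103. Both tests called 941 genes up and 556 down. A fold of at least 2 was reached by 273 higher and 121 lower genes. Without the 12 h libraries the linear trend was up for 692 genes and down for 489.

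Among genes called up by both tests with a mean of at least 1 CPM, the 10 largest rises included several matrix genes. Col8a2, a collagen chain, went from 21.7 ± 2.28 CPM (SD, n = 3) to 217 ± 3.05. This is a log2 change of 3.32 ± 0.09 (SE; edgeR adjusted p = 1.81e-17). Fmod, a collagen-binding proteoglycan, rose by 2.98 ± 0.26 on the log2 scale, Cxcl14, a chemokine, by 2.82 ± 0.16, and Cilp, a cartilage matrix protein, by 2.65 ± 0.12. Rxfp3, a receptor for relaxin peptides, rose by 2.80 ± 0.29, Trabd2b, a protease that inactivates Wnt proteins, by 2.32 ± 0.28, and Matn3, a matrilin, by 2.30 ± 0.25. Crispld2, a secreted protein, rose by 2.60 ± 0.16. Ms4a4d and Blk, a kinase known from B cells, rose by 2.23 ± 0.19 and 2.21 ± 0.25. The largest adjusted p among these was 2.12e-06. Without the 12 h libraries the linear trend was not called for Rxfp3 (1.80 with all libraries and 1.00 without, adjusted p = 0.0721), Blk (1.71 and 1.07, 0.0592) and Cilp (1.68 and 0.48, 0.558), and for Cilp not without any single library of 12 h (0.0617, 0.0611 and 0.0552) or the libraries numbered 2 (0.112).

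Among genes called down by both tests under the same limit, the 10 largest falls included several genes known to be induced by interferon. Ifi44 went from 18.9 ± 9.64 CPM (SD, n = 3) at 12 h to 1.03 ± 0.319 at 60 h, a log2 change of -4.19 ± 0.35 (SE; edgeR adjusted p = 5.89e-09). Usp18, which removes ISG15 from proteins, changed by -4.03 ± 0.49, Ifit1 by -3.21 ± 0.35, Dhx58, an RNA helicase of antiviral sensing, by -3.20 ± 0.31, and Irf7, a transcription factor of the interferon response, by -3.13 ± 0.26. Ifit3b and Ifit3 changed by -3.62 ± 0.53 and -2.76 ± 0.38, but as near-identical neighbours they may share reads, so their separate values are uncertain. The chemokine Ccl5 changed by -3.34 ± 0.35, Cdsn, an adhesion protein of skin, by -2.92 ± 0.44, and Car6, a secreted carbonic anhydrase, by -2.91 ± 0.19. Without the 12 h libraries the trend of Car6 was 0.30 (adjusted p = 0.788) against -2.15 with them, since most of its fall, from 25.9 to 5.63 CPM, came before 18 h. The trend was then also not called for Usp18 (-1.84 against -4.15, adjusted p = 0.0826), Ifit3b (-1.46 against -3.47, 0.0864), Ifit1 (-1.71 against -3.29, 0.0552) and Ifit3 (-1.42 against -2.75, 0.0506).

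In the 38 gene lists with at least 5 tested members, camera found 14 that moved up and 5 that moved down along the linear trend (adjusted p over the lists, preset correlation 0.01). With an estimated correlation 4 of these calls held, for interferon response, collagen and matrix, fatty acid synthesis and myokines. fry called 21 lists. In shuffles of single libraries among the time points, camera at the preset correlation called a median of 9 lists and up to 19. All 99 of these shuffles called at least 1 list, so a call at the preset correlation alone is weak evidence of a trend. The median change of all genes was -0.0143 and the direction of the 19 lists did not turn with median of ratios scaling. Trend values below are log2 changes over 48 h ± SE from all 27 libraries.

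Interferon response genes fell as a group. Of 29 members 24 fell, 28 adjusted over the list alone, with a median of -1.44 (camera adjusted p = 3.3e-28; adjusted p = 0.0371 with an estimated correlation). Irf7 changed by -3.07 ± 0.36, Oasl2, a relative of the oligoadenylate synthetases, by -2.50 ± 0.31, Gbp2, a guanylate-binding GTPase, by -1.44 ± 0.15, and Ddx58, which encodes the RNA sensor RIG-I, by -1.12 ± 0.14. In the libraries of each replicate number the median change from 12 to 60 h was -1.14, -1.80 and -1.34. Of 28 members 15 fell without the 12 h libraries, with a median of -0.75. Inflammation genes were not called as a list (camera adjusted p = 0.112), with 3 of 18 up and 5 down, 3 and 5 adjusted over the list alone; Ccl5 changed by -3.87 ± 0.32, Cxcl5 by -1.71 ± 0.21, Ccl9 by -1.11 ± 0.15 and Ptgs2, the inducible cyclooxygenase, by 0.95 ± 0.14. Of the immune and endothelial markers, 5 of 14 had enough reads to test, at a median of 0.744 CPM. The 5 had trends from -0.50 ± 0.26 (Itgam) to 0.41 ± 0.31 (Tek) and the list was not called (camera adjusted p = 0.821).

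Lipid synthesis rose. In the cholesterol list 22 of 24 genes rose, 23 adjusted over the list alone, with a median of 1.03 (camera adjusted p = 1.3e-20; adjusted p = 0.104 with an estimated correlation). Cyp51, lanosterol demethylase, rose by 1.58 ± 0.22, Tm7sf2, a sterol reductase, by 1.23 ± 0.18, and Ebp, a sterol isomerase, by 0.70 ± 0.11. Cyp51 went from 196 ± 22.9 CPM (SD, n = 3) at 12 h to 767 ± 45.8 at 36 h and stood at 783 ± 27.2 at 60 h, and without the 12 h libraries 9 of the 24 genes rose (median 0.50). In fatty acid synthesis 12 of 17 genes rose, 12 adjusted over the list alone, with a median of 0.62 (camera adjusted p = 4.69e-12; adjusted p = 0.0371 with an estimated correlation), and 8 rose without the 12 h libraries (median 0.36). Scd2, a fatty acid desaturase, rose by 1.47 ± 0.17, Fads2, also a desaturase, by 1.27 ± 0.15, Srebf1, the transcription factor of lipogenesis, by 0.98 ± 0.11, and Acaca, acetyl-CoA carboxylase, by 0.55 ± 0.08. Fatty acid oxidation was not called (camera adjusted p = 0.234), with 1 of 26 up and 5 down, 1 and 5 adjusted over the list alone. Cpt1a, which admits fatty acids to mitochondria, changed by -0.86 ± 0.11, and Angptl4, an inhibitor of lipoprotein lipase, by -0.68 ± 0.13, which was -0.37 and not called without the 12 h libraries (adjusted p = 0.127).

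**Figure D3:**
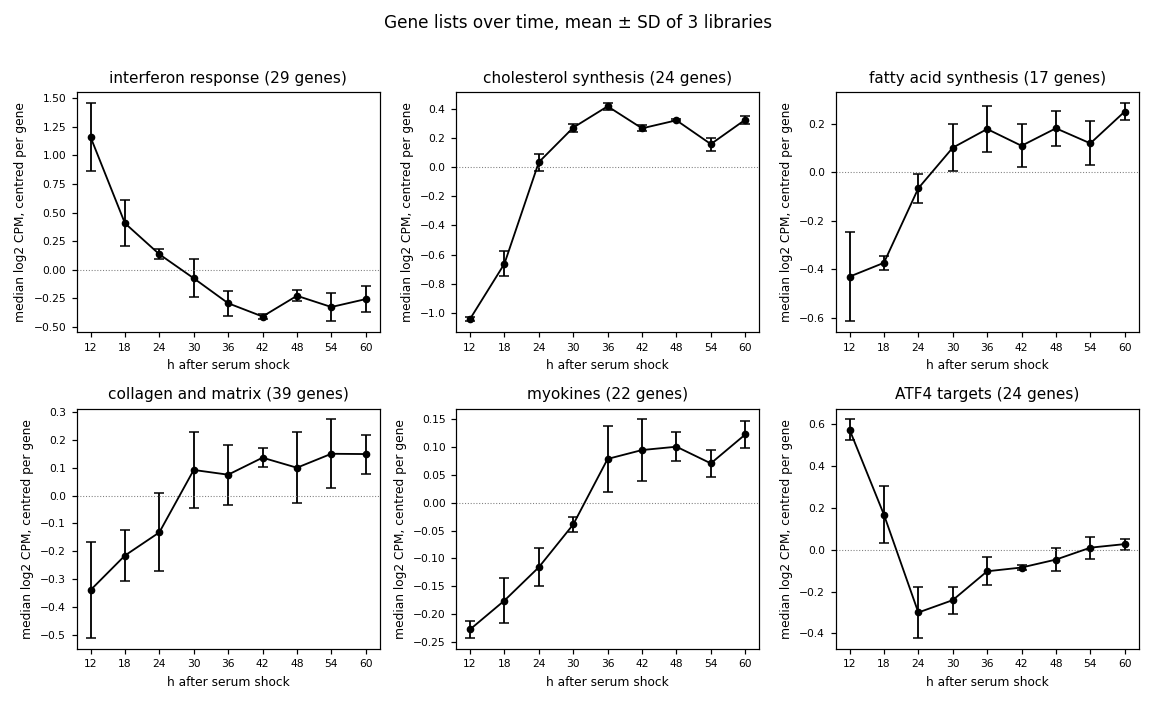
Median log2 CPM of 6 gene lists, each gene centred on its mean over 27 libraries (vertical axes, not from 0), against hours after the serum pulse (horizontal axes); points are means of 3 libraries and bars their SD. The interferon list goes from 1.16 at 12 h to -0.26 at 60 h, the cholesterol list from -1.04 to 0.32, and the ATF4 list from 0.58 at 12 h through -0.30 at 24 h to 0.03.

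Matrix genes rose with markers of smooth muscle. In the collagen and matrix list 21 of 39 rose and 2 fell, 23 and 2 adjusted over the list alone, with a median of 0.39 (camera adjusted p = 2.34e-20; adjusted p = 0.0371 with an estimated correlation). Timp3, an inhibitor of metalloproteinases, rose by 1.79 ± 0.11, Col8a1, a partner of Col8a2, by 1.34 ± 0.06, Postn, periostin, by 0.92 ± 0.08, and Sparc, a collagen-binding glycoprotein, by 0.54 ± 0.05. Of 8 smooth muscle markers 4 rose, 5 adjusted over the list alone, with a median of 0.69 (camera adjusted p = 5.58e-06; adjusted p = 0.0581 with an estimated correlation), or 0.45 without the 12 h libraries. Cnn1, calponin, rose by 1.65 ± 0.25, Tagln, transgelin, by 1.36 ± 0.17, Mcam, a cell adhesion molecule, by 1.14 ± 0.13, and Acta2, smooth muscle actin, by 0.78 ± 0.14. Fibroblast markers (2 of 10 up, 1 down, 3 and 2 adjusted over the list alone; camera adjusted p = 0.664) and osteoblast markers (2 of 6 up, 1 down, 2 and 1 adjusted over the list alone; 0.243) were not called. Mfap5, of elastic microfibrils, changed by 1.19 ± 0.14, and the bone genes Dmp1 and Phex by 1.72 ± 0.23 and -1.29 ± 0.24. For fibroblast markers the median was -0.13 and the mean 0.14.

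Lists of targets of serum, TGF beta and Wnt signals were called up at the preset correlation but not with estimated ones. Early response genes and targets of SRF rose for 15 of 31 members, 17 adjusted over the list alone, with a median of 0.22 (camera adjusted p = 2.32e-10; adjusted p = 0.104 with an estimated correlation), and 9 rose without the 12 h libraries. Ccn2 and Ccn1, matricellular proteins, rose by 1.65 ± 0.21 and 1.31 ± 0.17, and Ier3 by 0.83 ± 0.08. TGF beta targets rose for 7 of 24 members, 7 adjusted over the list alone (median 0.32, camera adjusted p = 8.44e-04; adjusted p = 0.184 with an estimated correlation), and 5 rose and 1 fell without the 12 h libraries (median 0.16). At 60 h against 12 h, 10 were higher and 3 lower. Inhba, a subunit of activin, rose by 1.25 ± 0.16. Of 17 Wnt targets 6 rose and 1 fell, 7 and 1 adjusted over the list alone (median 0.29, or 0.18 without the 12 h libraries; camera adjusted p = 2.59e-04; adjusted p = 0.0978 with an estimated correlation). Nkd2, an inhibitor of the pathway, rose 3.61-fold from 12 to 60 h (log2 1.85 ± 0.08). By the trend Wnt11 rose by 1.09 ± 0.17 and Wnt4 by 0.93 ± 0.13.

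Muscle genes went both ways. Myog, myogenin, the transcription factor of early differentiation, changed by -0.91 ± 0.06, from 744 ± 11.4 CPM (SD, n = 3) at 12 h to 420 ± 30.1 at 60 h, while Myf6, the regulator of later differentiation, rose by 1.28 ± 0.23 and Mef2c by 0.44 ± 0.07. Mef2a changed by -0.43 ± 0.11, which was -0.40 and not called without the 12 h libraries (adjusted p = 0.0748). The myogenic regulators were not called as a list (2 of 14 up and 2 down, 2 and 2 adjusted over the list alone; camera adjusted p = 0.553). Mymx, myomixer, a membrane protein of myoblast fusion, changed by -1.36 ± 0.09 and Cdh2, N-cadherin, by -0.48 ± 0.06, while the integrin Itga4 rose by 0.77 ± 0.14. Fusion genes as a list were not called (3 of 16 up and 3 down, 3 and 4 adjusted over the list alone; camera adjusted p = 0.166) but were without the 12 h libraries (down, 0.0434). Of 53 sarcomere genes 16 rose and 7 fell, 16 and 9 adjusted over the list alone, and the list was not called (camera adjusted p = 0.0802). Mybpc1, a myosin-binding protein of slow fibres, rose by 1.09 ± 0.10, Myh4, a myosin heavy chain of fast fibres, by 0.81 ± 0.08 and Trdn, triadin, by 0.55 ± 0.08, while Mybph changed by -0.45 ± 0.06. Of the sarcomere genes 10 rose and 4 fell without the 12 h libraries. Myokines, secreted factors of muscle, rose for 12 of 22 members and fell for 3, 15 and 3 adjusted over the list alone (median 0.48, camera adjusted p = 9.19e-06; adjusted p = 0.00359 with an estimated correlation). Fgf2 rose by 0.69 ± 0.08 and Bdnf by 0.52 ± 0.07, while Fgf21, a hormone induced by stress, changed by -3.05 ± 0.25.

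Genes of reserve cells, the quiescent mononuclear cells of such cultures, were not called (2 of 15 up and 3 down, 2 and 3 adjusted over the list alone; camera adjusted p = 0.734). Cd34 changed by -0.48 ± 0.12, which was -0.11 and not called without the 12 h libraries (adjusted p = 0.705), and without these 2 genes of the list fell. Proliferation genes rose for 8 of 37 members and fell for 2, 9 and 2 adjusted over the list alone, with a median of 0.17 (camera adjusted p = 0.045; adjusted p = 0.555 with an estimated correlation). At 60 h against 12 h the proliferation list went both ways, with 15 genes higher and 9 lower. Cenpa, a histone of centromeres, rose by 0.67 ± 0.15, Cdc20, an activator of the anaphase-promoting complex, by 0.60 ± 0.15, and the mitotic kinase Aurka by 0.46 ± 0.12. When the 12 h libraries were left out, the list had a median of 0.10 and was not called (camera adjusted p = 0.0646), nor were Cenpa (0.29, adjusted p = 0.234), Cdc20 (0.19, 0.517) and Aurka (0.15, 0.571). Replication-dependent histones, a multigene family whose members may share reads, rose for 4 of 41, 3 adjusted over the list alone (median 0.23, camera adjusted p = 8.44e-04; adjusted p = 0.639 with an estimated correlation), and the list was not called without the 12 h libraries (median 0.05, 0.467). Genes of cell cycle exit were not called (1 of 16 up and 2 down, 2 and 3 adjusted over the list alone; camera adjusted p = 0.289). Gadd45b, a stress response gene, changed by 0.49 ± 0.09.

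Glycolysis genes rose for 10 of 21 members, 14 up and 1 down adjusted over the list alone, with a median of 0.25 (camera adjusted p = 9.42e-06; adjusted p = 0.184 with an estimated correlation), and 6 rose without the 12 h libraries. Pgam1, phosphoglycerate mutase, rose by 0.57 ± 0.10, Ldha, lactate dehydrogenase, by 0.42 ± 0.08 and Pkm, pyruvate kinase, by 0.38 ± 0.08. Genes of glucose uptake and insulin signalling rose for 10 of 29 and fell for 2, 11 and 2 adjusted over the list alone (median 0.12, camera adjusted p = 0.00209; adjusted p = 0.238 with an estimated correlation). The glucose transporter Slc2a3 rose from 2.77 ± 0.165 CPM (SD, n = 3) at 12 h to 7.89 ± 1.16 at 60 h and Slc2a1 by 0.69 ± 0.12, Igfbp3, which binds insulin-like growth factors, rose by 1.88 ± 0.23, and the insulin signalling kinase Akt2 changed by -0.23 ± 0.05. This list was not called without the 12 h libraries (camera adjusted p = 0.0579, 4 up and 2 down). Hypoxia targets rose for 9 of 16, 9 adjusted over the list alone (median 0.32, camera adjusted p = 0.00847; adjusted p = 0.447 with an estimated correlation), among them P4ha2, a collagen prolyl hydroxylase, by 0.43 ± 0.09. The number that rose was 3 without the 12 h libraries (median 0.21) and 4 without the libraries numbered 2. The rise of the hypoxia list was not steady. Its median log2 level, centred per gene, was 0.175, 0.138 and 0.202 at 36, 48 and 60 h. At 42 and 54 h it was -0.068 and -0.10, near the -0.092 of 12 h. This alternation is described under the other observations. Nuclear genes of oxidative phosphorylation had a median of -0.09 (camera adjusted p = 0.0177; adjusted p = 0.714 with an estimated correlation) with 2 of 49 down, 1 adjusted over the list alone, and the list was not called without the 12 h libraries (0.054). Uqcrq, of respiratory complex III, changed by -0.45 ± 0.12, which was -0.30 and not called without the 12 h libraries (adjusted p = 0.233). The TCA cycle was not called (1 of 22 up and 2 down, 1 and 2 adjusted over the list alone; camera adjusted p = 0.21). Suclg2, a subunit of succinyl-CoA ligase, changed by -0.61 ± 0.10.

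ATF4 targets, genes of amino acid supply, fell for 10 of 24 members and rose for 1, 11 and 3 adjusted over the list alone, with a median of -0.18 (camera adjusted p = 0.00363; adjusted p = 0.579 with an estimated correlation). Mthfd2, of mitochondrial folate metabolism, changed by -0.67 ± 0.09 and Fgf21 by -3.05 ± 0.25, while Atf4 itself rose by 0.44 ± 0.08. Without the 12 h libraries the direction of the ATF4 list turned, with 8 up and 2 down, a median of 0.18 and a camera adjusted p of 0.0137, and without the libraries numbered 2 it had 2 up and 6 down. NRF2 targets fell for 4 of 22, 4 adjusted over the list alone (median -0.14, camera adjusted p = 0.0268; adjusted p = 0.514 with an estimated correlation), led by Nqo1, a quinone reductase, at -1.13 ± 0.19 and Gstm1, a glutathione transferase, at -0.79 ± 0.14. When the 12 h libraries were left out, 5 rose and 2 fell and the NRF2 list was not called (0.659). The unfolded protein response rose for 5 of 22, 5 adjusted over the list alone (median 0.10, camera adjusted p = 0.0118; adjusted p = 0.184 with an estimated correlation), and for 2 without the 12 h libraries. Xbp1, a transcription factor of that response, and Edem1, which sorts misfolded proteins, each changed by 0.28 ± 0.06, which was 0.22 and 0.23 and missed the threshold without the 12 h libraries (adjusted p = 0.0659 and 0.0663).

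Heat shock genes (1 of 24 up, 4 down, 1 and 5 adjusted over the list alone; camera adjusted p = 0.191), glucocorticoid targets (4 of 14 up, 1 down, 5 and 1 adjusted over the list alone; 0.206) and genes of atrophy and autophagy (1 of 25 up, 1 down, 1 and 1 adjusted over the list alone; 0.618) were not called. Hspb7, a small heat shock protein, changed by 0.75 ± 0.15, Klf9, a transcription factor induced by glucocorticoids, by 0.57 ± 0.10 and Fkbp5, a cochaperone of the glucocorticoid receptor, by 0.26 ± 0.08.

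Ribosomal proteins fell for 15 of 51 members, 17 adjusted over the list alone, with a median of -0.25 (camera adjusted p = 9.19e-06; adjusted p = 0.417 with an estimated correlation), and for 4 without the 12 h libraries. At 60 h against 12 h, 2 of the 51 were lower. Rpl22 and Rplp1 changed by -0.44 ± 0.09 and -0.39 ± 0.10; pseudogenes may share reads with this family. Ribosome biogenesis was not called (1 of 28 up and 1 down, 1 and 1 adjusted over the list alone; camera adjusted p = 0.821) but was without the 12 h libraries (up, 6.25e-04, with 3 members up). Chromatin regulators were not called (1 of 42 up, 3 down, 1 and 2 adjusted over the list alone; camera adjusted p = 0.522), with the histone demethylases Kdm4a and Kdm5a at -0.30 ± 0.05 and -0.25 ± 0.05. Imprinted growth genes were not called (1 of 11 up and 1 down, 1 and 1 adjusted over the list alone; 0.716), with the growth factor Igf2 at -0.85 ± 0.19, and Mest at 0.94 ± 0.22, which was 0.34 and not called without the 12 h libraries (adjusted p = 0.381). Core clock genes had no shared trend (1 of 19 up and 2 down, 1 and 2 adjusted over the list alone; camera adjusted p = 0.786). Bhlhe40, a repressor of clock activators, changed by 0.64 ± 0.13 and Hlf, a relative of Dbp, by -1.83 ± 0.44. Clock modifiers were not called (1 of 15 down, 1 adjusted over the list alone; camera adjusted p = 0.716), and the member was Nono, which binds PER proteins, at -0.20 ± 0.05, which was -0.16 and not called without the 12 h libraries (adjusted p = 0.104).

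Taken as 9 time point means, the linear trend was called by limma for 585 genes up and 324 down. Of the genes named by size of change, Rxfp3, Cilp, Crispld2, Blk, Ifi44, Usp18, Ifit1, Ifit3, Ifit3b and Car6 were then not called (adjusted p from 0.07 to 0.429). Their changes kept their direction in that fit. The rises lay between 1.82 (Blk) and 2.39 (Crispld2) in log2 over 48 h, and the falls between -1.49 (Car6) and -3.55 (Ifi44). Of the list members named, Cyp51, Tm7sf2, Ebp, Angptl4, Ccn1, Ccn2, Tagln, Cnn1, Acta2, Ptgs2, Pgam1, Akt2, Atf4, Nqo1, Gstm1, Fkbp5, Cd34, Cenpa, Cdc20, Aurka, Mest and Nono were also not called in that fit (adjusted p from 0.0539 to 0.217).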

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

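The test of the days and the decay term differ in when they were chosen: the test was planned, and the decay term and the measure of damping were chosen after the result was seen.

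A test of the difference between the first and second day singled out 637 genes. For the 6 named by rule the second day minus the first, in log2 of the fitted swing, was -1.36 for Nsdhl, -1.32 for Fdft1, -1.11 for Elovl6, -1.80 for Lss, -2.55 for Cth and -1.84 for Pck2. For damping of the clock, the median of the same difference over the 7 rhythmic clock genes was -0.042. None of the 7 was called (edgeR adjusted p of 0.765 or more), though the test found 5% of differences of 1.5-fold in simulated data. Damping stays open, because the 7 were picked by a fit of 1 wave over both days, which favours genes whose swing is steady. A change after the pulse that decays may account for part of the difference: with a decay term in the model the median difference between the waves of the 637 genes went from 0.90 to 0.52 in log2 and was smaller for 555, and 58 of them were still called, while the median error of the first-day swing went from 0.14 to 0.19. The 6 named genes were all still called, with smaller differences such as -0.73 for Nsdhl and -0.68 for Pck2, so for these a decay of this shape is not the whole cause. Whether such a change came from the pulse, the handling or continued differentiation stays open, because no culture without the pulse was sequenced.

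When the 27 libraries were shuffled among time points 100 times, 1 arrangement, the real one, gave 637 genes or more, and the highest other gave 439, so chance was excluded for shuffles that move single libraries freely. These shuffles ignore the replicate number and part the libraries of a time point, and whole time points were not shuffled for this test.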

How the results depend on the processing

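The fits named here as added were chosen after the result was seen. Leaving out each library gave 6 to 9 rhythmic genes, 1900 to 2398 genes with any change, 1132 to 1392 with a trend up and 916 to 1265 down, 903 to 1201 higher and 562 to 898 lower at 60 h, 464 to 706 differing between the days, 16 to 20 lists along the trend and 1 to 1 among the rhythmic genes. Counts that moved over 1.5 times, with the cause not tested, were as follows. DESeq2 gave 11 rhythmic genes. A period of 20 h gave 0 rhythmic genes in edgeR (406 with unadjusted p under 0.05, lowest adjusted p = 0.141; 7 in limma-voom at 24 h) and 0 lists. Time point means gave 0 rhythmic genes in limma (247 with unadjusted p under 0.05), where limma-voom on all libraries gave 7. The fit of means also gave 0 lists, 585 genes up and 324 down. It has fewer units, and whether this or a spread shared by the libraries of a time point lowered the counts was not tested. A cubic term (added) gave 18 rhythmic genes and 4 lists. Without the 12 h libraries there were 1189 genes with any change (added), 692 up and 489 down, and the trend of Car6 reversed to 0.30. The decay term (added) gave 93 genes for the days, 58 of them among the 637. Without the 9 libraries numbered 2 (added) 1500 changed and 362 differed between the days. Adjusted p under 0.01, a stricter threshold, gave 1531 with any change, 883 up, 559 down, 795 higher, 448 lower and 332 for the days. A swing of at least 1.5-fold left 4 rhythmic genes, and estimated correlations left 4 lists.

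The replicate number as a block gave 5166 genes with any change, 1861 down along the trend, 2032 higher and 1716 lower at 60 h and 1494 for the days; with the decay term (added) it gave 12 rhythmic genes and 323 for the days. It left 7 rhythmic genes. Of 108 pairs of libraries with the same number 91 correlated over 0.1, and 26 of 27 libraries were closest to their own number, a hint from the data and not from the design. Between 12 and 60 h these correlations were 0.017, 0.331 and 0.324.

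Rhythmic genes shared with the 7 were 4 of 5 without 12 h, 4 of 7 from 24 h on (added), 4 of 5 at 28 h and 6 of 7 with the decay term. Among values of named genes, leaving out a library ended 66 calls of the trend and 4 of the rhythm and turned 0; the other alternatives ended 156 and 26 and turned 1, and none ended a call of 60 h against 12 h or of the days. At this depth genes with few reads were not tested, and in simulations a rhythm of 1.3-fold was missed in 32% of genes.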

Other observations

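In this part the tests of alternation, its chance divisions and its fit without early collections were chosen after the result was seen; the tests of the interferon genes were written as predictions first.

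A fitted alternation between collections 6 h apart was called for 181 genes. Of these (edgeR, adjusted p under 0.05, 27 libraries, in a model that also holds linear, decay and 24 h terms), 76 were fitted higher and 105 lower at 12, 24, 36, 48 and 60 h than at 18, 30, 42 and 54 h. Pdk1, a kinase that turns pyruvate away from respiration, was higher by 0.41 ± 0.042 (log2, SE; 58.0 against 45.8 CPM), and Bnip3, of mitochondrial autophagy, by 0.53 ± 0.064. Slc16a3, a lactate transporter, was higher by 0.50 ± 0.064, Ak4, a mitochondrial adenylate kinase, by 0.78 ± 0.115, and Tgm2, a transglutaminase, by 0.39 ± 0.035. Not every step went this way: Pdk1 was lower at 12 than at 18 h (36.3 and 39.6 CPM), as was Tgm2 (43.2 and 50.4), and Slc16a3 was lower at 24 than at 30 h (27.1 and 28.4). Ahrr, which represses the aryl hydrocarbon receptor, was lower, at -1.09 ± 0.138 (1.88 against 4.19 CPM), as were Ccn2 (-0.48 ± 0.082) and Cyp1b1, a target of that receptor (-0.25 ± 0.044). Hypoxia targets were higher as a list, 7 of 16 with a median of 0.18 (camera adjusted p = 1.39e-30; adjusted p = 3.63e-07 with an estimated correlation). The fitted alternation was also positive for cholesterol synthesis (7 of 24, median 0.19, camera adjusted p = 1.64e-23; adjusted p = 0.00192 with an estimated correlation), although the level of that list was lower at 12 than at 18 h (-1.04 and -0.66) and at 24 than at 30 h (0.03 and 0.27). Early response genes went the other way (median -0.09, camera adjusted p = 7.03e-05; adjusted p = 0.47 with an estimated correlation). These genes were named after their values were seen.

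A fit of the alternation from 24 h on called 163 genes, 109 of them among the 181, so the earliest collections alone do not account for those 109. The rest of the 181 were not called in that fit. The overlap is not an independent repeat, since the libraries from 24 h on also served to pick the 181. Of 100 divisions of the time points 4 gave as many genes, the real one included, and the highest other gave 219; since the division was picked after it was seen, this does not exclude chance. A 12 h rhythm cannot be told apart from it, since only 2 phases of a 12 h cycle were sampled. Transcript length stays open too, since its rho of -0.172 lies between the limits set for and against it (0.3 and 0.1 in size). Whether collections shared a session, such as a day and a night one, is not recorded and stays open.

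The fall of interferon response genes was weighed against 2 explanations. One series of libraries alone was argued against, since the highest of the 3 median changes, 1 per replicate number, was -1.14, with 28, 28 and 29 of 29 genes lower. Leukocytes in the early cultures stay open: the pooled change of 8 leukocyte markers was -0.12 in log2 (140 counts at 12 h and 133 at 60 h; 95% interval -0.47 to 0.24, counting error only), but the markers lie near the floor, at 2.08 CPM together at 12 h, so the limit set beforehand decides nothing. A response to the serum pulse or to earlier handling that fades with time stays open, since no culture without the pulse was sequenced.

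Shuffling the 27 libraries among time points 100 times gave as many genes with any change in 1 arrangement, the real one (2338 genes, highest other 138), a trend up in 1 (1355, 976) and a trend down in 1 (1103, 978), so chance was excluded for these under shuffles that move single libraries freely, without regard to the replicate number; whole time points were not shuffled for the trend. As many rhythmic genes came in 3, the real one included (7 genes, highest other 1600). This highest split may point to a structure of the samples, which was neither tested nor traced. Lists along the trend came in 2 (19 lists, highest other 19, median 9) and lists among rhythmic genes in 2 (1 list, highest other 10). For 60 h against 12 h, 10 splits are too few to exclude chance: 1203 genes were higher and 830 lower in the real one, 1 of 10 in each case, and the highest other gave 0. Shuffling whole time points with their 3 libraries gave 7 or more rhythmic genes in 72 of 100 (median 59, highest 2427), 7 core clock genes in 1, and a list in 62. These shuffles also break up the linear trends, which the linear term then no longer takes up and which can be fitted as waves. How much of these counts came from that was not tested, so they do not measure chance alone.

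In the libraries numbered 2, 2533 genes were higher and 2707 lower than the mean of the other 2 libraries at all 9 time points. By chance 24.8 each way would be, if higher and lower were equally likely at each time point. This difference had a rho of -0.486 with transcript length and -0.154 with GC content over 12675 genes. In 4 equal groups of genes, from the shortest to the longest transcripts, its median was 0.15, 0.06, 0.00 and -0.13. For nuclear genes of oxidative phosphorylation the median was 0.23, for ribosomal proteins 0.23, for chromatin regulators -0.17 and for collagen and matrix genes -0.14.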
